A study of Mus musculus with 18 samples.

How the data were processed

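Dura mater from 18 male mice was measured on an Affymetrix mouse gene-level array, with 1 mouse per array and 3 arrays in each of 6 groups (wild-type, mast cell-deficient and engrafted mice, each naive or after stroke). The deposited values are log2 summary values per probe set; RMA, affy and R 3.0.0 are named in the submitters' processing notes, which do not say what each did. The notes give no scan date or batch, so no batch could be tested. The table held 34760 probe sets. Of these, 21640 had exactly 1 gene symbol and were tested (19938 genes), 1321 had several symbols and 11799 were not in the probe annotation, and these were left out of the comparisons. Symbols were checked against the mouse RefSeq table of GRCm38.p6, which held the gene identifiers of 21553 tested probe sets. No values were rescaled and no probe set was removed for low signal.

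A model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (12 residual and 3.41 prior degrees of freedom). There were 15 comparisons: stroke against naive within each of the 3 categories and averaged over them, the categories against each other within naive dura, within stroke dura and (deficient against wild type, engrafted against deficient) averaged over both, and the 3 interactions between category and stroke. P values were adjusted by Benjamini and Hochberg within each comparison over the tested probe sets, with a threshold of 0.05 and no minimum change. If nothing differed, 1082 tested probe sets would be expected at an unadjusted p under 0.05. For 29 gene lists with 417 members, of which 377 were measured, camera was run with a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p over the members of a list alone are given as "adjusted over the list alone". Where a gene had several probe sets (953 genes), the one with the highest mean over the arrays stands for it. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

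The lists, comparisons, thresholds and alternatives, except those named below, were chosen before the data were examined. So was the rule for naming genes: Kit and each measured gene of the mast cell list; the 10 that rose most and the 10 that fell most among those past the threshold, or the 5 with the smallest p where fewer than 5 passed; in each list described, up to 4 members with the smallest p; and Il6 and Ccl7. Ttr and Htr2c fall outside the rule and were chosen after their values were seen, as were 3 further lists (pineal gland, choroid plexus and keratinocyte genes). In the pineal gland list 0 members passed in any comparison; after stroke in engrafted dura its median was -0.36 (camera adjusted p = 0.000414, adjusted p = 0.219 with an estimated correlation).

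The fit was tested on simulated data with 21640 probe sets, of which 200 were changed, in 5 draws. The simulated noise was independent between probe sets. Differences between arrays that many genes share were not simulated, so the rates below do not cover them. For stroke in wild type, 60.4%, 95.2% and 99.2% of changes of 0.5, 1 and 2 on the log2 scale were recovered, with 5.55% false calls. For the deficient against wild-type interaction the shares were 32.4%, 90.4% and 96%, with 3.05% false calls, and for the averaged engrafted against deficient comparison 90%, 97.6% and 100%, with 5.28%. Alternatives tried were leaving out each array in turn, leaving out dim probe sets, a block for the replicate number, a second quantile normalization, a trended and robust variance, array weights, only the compared groups in the fit, all probe sets, and a minimum change of 1.5-fold. After the data were seen, fits with choroid plexus and neuron scores as covariates and without the 5 arrays lowest in Ttr were added. The fit without those 5 left naive deficient dura with 1 array. In comparisons that use this group, calls lost in that fit cannot tell a dependence on choroid plexus tissue from lost replication. The named genes refitted under each alternative were extended to every gene under the naming rule that passed or had a p under 0.01. Other genes that passed were not refitted one by one.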

Results

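Gene expression was measured in the dura mater, the outer membrane that encloses the brain, of 18 male mice aged 17 to 21 weeks. Each dura was hybridised to an Affymetrix mouse array of its own, so that 1 array stands for 1 mouse. The mice fell into 3 categories. Wild-type mice carried normal Kit genes. Mast cell-deficient mice carried the W and W-v alleles of Kit, the receptor that mast cells need to survive, on the same WBB6F1 background. Engrafted mice were deficient mice that had received mast cells intravenously 8 to 10 weeks earlier. In each category, 3 mice were naive and 3 had undergone a stroke, made by closing the middle cerebral artery with a filament for 30 minutes, 2 days before the dura was taken. Age-matched naive mice served as controls, and mice with a sham operation were not analysed here, so every difference between stroke and naive dura includes any effect of the operation itself. The study asked how stroke changes gene expression in the meninges and how mast cells influence these changes. Log2 values on the array ran from 3.42 to 14.06, array medians lay between 7.77 and 7.91, and arrays of a group correlated across probe sets with r of 0.985 to 0.995. The number of arrays limits the precision: the median standard error (SE) of a log2 difference was 0.10 for 3 arrays against 3 and 0.14 for a difference between 2 stroke responses.

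Transcripts of mast cell proteases set the deficient mice apart from the other categories. Log2 levels of Cpa3 (probe set 10497451), carboxypeptidase A of mast cell granules, were 9.44 ± 0.33 in naive wild type, 5.76 ± 0.09 in naive deficient and 9.78 ± 1.07 in naive engrafted dura, and 8.95 ± 0.49, 5.74 ± 0.07 and 9.65 ± 0.16 after stroke (SD, n = 3 each). Mcpt2 (probe set 10415438), a mast cell chymase, was likewise lowest in deficient dura, with 9.79 ± 0.23, 5.06 ± 0.12 and 9.61 ± 1.08 in naive dura and 9.23 ± 0.40, 5.39 ± 0.07 and 9.78 ± 0.20 after stroke. The deficient levels of Cpa3, Mcpt2 and Mcpt4, at most 5.82, 5.44 and 5.94, lay below the lower quartile of every array (6.09 to 6.24) and were not shown to be above background, so differences of these 3 genes from deficient dura are lower bounds. Kit itself (probe set 10522530) lay between 9.36 and 9.83 in the naive wild-type arrays, between 8.91 and 9.19 in naive deficient and between 9.07 and 9.19 in naive engrafted arrays. After stroke it lay between 8.80 and 9.17, between 8.63 and 8.75 and between 8.76 and 9.32. The position of the probe set relative to the altered parts of Kit is not used here, so its level does not check the genotype. Tph1, a member of the mast cell list that the pineal gland also expresses, had group means of 12.76 to 13.21.

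**Figure D1:**
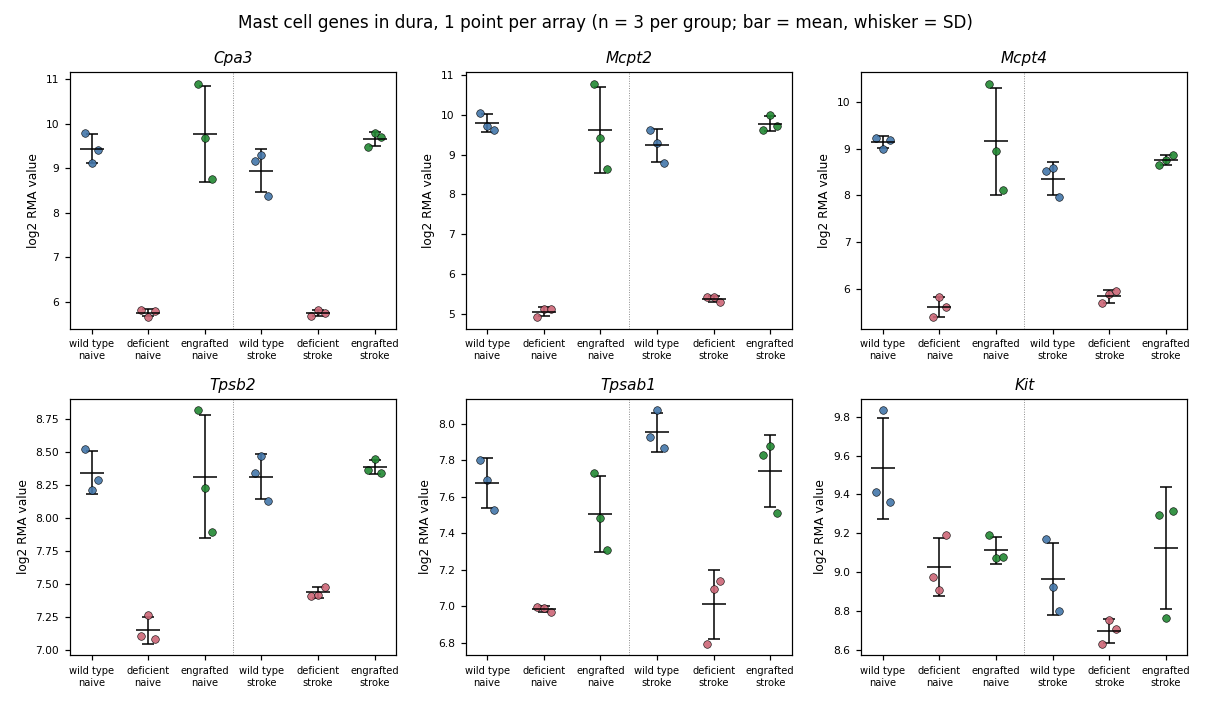
Log2 expression of 6 mast cell genes (vertical axes, which differ in range) in each of the 18 arrays, by category and treatment; points are arrays, bars are group means and whiskers are SDs (n = 3). Cpa3, Mcpt2, Mcpt4 and Tpsb2 were lower in each deficient array than in any wild-type or engrafted array.

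The first comparison asked which transcripts differ in naive dura when mast cells are missing. In naive deficient dura, 3 proteases were lower than in wild type by differences that are lower bounds in size, -4.73 ± 0.35 (log2, SE) for Mcpt2, -3.68 ± 0.37 for Cpa3 and -3.54 ± 0.37 for Mcpt4, another chymase, with limma adjusted p of 1.59e-05, 0.000419 and 0.000461. Tpsb2, a tryptase, was also lower (-1.19 ± 0.16, adjusted p = 0.0121). These 4 were all the probe sets that passed among 21640, and 0 were higher, beside 1476 at an unadjusted p under 0.05. With array weights 36 passed, 15 higher and 21 lower. Of the 22 measured genes of the mast cell list, 0 rose and 4 fell, and 14 fell when adjusted over the list alone. This list as a whole lay lower. The camera adjusted p was 4.66e-19, with adjusted p = 0.0159 with an estimated correlation. In the mature neutrophil list, 0 of 13 genes passed over all genes, while adjusted over the list alone 7 fell and 1 rose, with a median of -0.997. Camera gave this list an adjusted p of 9.24e-09, and adjusted p = 0.287 with an estimated correlation. Erythroid genes had a median of -0.22 beside them, with 0 of 7 passing by either adjustment, over all genes or adjusted over the list alone. Bone genes had a median of 0.31, with 0 of 10 passing over all genes and 5 higher when adjusted over the list alone. The list's camera adjusted p was 5.24e-09, against adjusted p = 0.165 with an estimated correlation. Genes of the choroid plexus, the brain tissue that secretes cerebrospinal fluid, had a median of -2.0 in the same comparison, with 0 of 10 passing. Naive deficient array 1 and 3 were among the 5 arrays lowest in Ttr, a choroid plexus gene. The call of Tpsb2 was lost without naive wild-type array 1 or 3 (adjusted p = 0.0516 and 0.071) or naive deficient array 1 or 3 (adjusted p = 0.112 and 0.0954), after a second quantile normalization (0.0547), with choroid plexus and neuron scores as covariates (0.057) and without the 5 arrays lowest in Ttr (0.212). Without naive wild-type array 1, 10 probe sets passed.

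Engraftment was compared with deficiency in naive dura to ask which transcripts the transferred cells bring back. The same 4 genes were higher in engrafted than in deficient dura: Mcpt2 by at least 4.54 ± 0.35, Cpa3 by at least 4.02 ± 0.37, Mcpt4 by at least 3.55 ± 0.37 and Tpsb2 by 1.16 ± 0.16 (adjusted p = 2.8e-05, 0.000128, 0.000433 and 0.0162). No other probe set passed, and 1016 had an unadjusted p under 0.05, fewer than the 1082 expected if nothing differed. In the mast cell list, 4 of 22 genes rose and 11 rose when adjusted over the list alone. By camera the list had an adjusted p of 7.76e-21, and adjusted p = 0.011 with an estimated correlation. The basophil list, which shares Fcer1a and Ms4a2 with it, lay higher as a set, with 0 of 8 genes passing over all genes and 1 passing adjusted over the list alone. As a set the list had a camera adjusted p of 0.000188, and adjusted p = 0.0213 with an estimated correlation. With only these 6 arrays in the fit, 0 probe sets passed, and adjusted p of Mcpt2, Cpa3, Mcpt4 and Tpsb2 were 0.585, 0.629, 0.844 and 0.844. The engrafted arrays of Mcpt2 were 10.77, 9.40 and 8.64. Tpsb2 also lost its call without naive deficient array 1 or 3 (0.145 and 0.147), without naive engrafted array 2 (0.0742), after a second quantile normalization (0.0578) and without the 5 arrays lowest in Ttr (0.159), and 7 probe sets passed without naive engrafted array 3. Between naive engrafted and naive wild-type dura, limma called 0 probe sets, while 4143 had an unadjusted p under 0.05. That is well above the 1082 expected if nothing differed, so the 0 calls do not show that these categories were alike. The smallest p in that comparison belonged to Vdr, the vitamin D receptor, at 1.04 ± 0.14 (adjusted p = 0.0647). Without naive wild-type array 2 or 3 or naive engrafted array 2 or 3 it also called 0. Some other fits called more: 1 without naive engrafted array 1, without the 5 arrays lowest in Ttr, with dim probe sets left out or with the trended variance, 2 with the replicate block, 3 with only these arrays, 4 after a second quantile normalization, 6 without naive wild-type array 1, 20 with the covariates and 164 with array weights.

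The next question was how stroke changes the dura of wild-type mice. Mmp3 (probe set 10583071), a matrix-degrading metalloproteinase, showed the largest rise, 4.21 ± 0.18, from 6.80 ± 0.10 to 11.01 ± 0.16 (SD, n = 3; adjusted p = 3.13e-09). Krtdap, a keratinocyte protein, rose by 3.36 ± 0.24, Reg3g, an antimicrobial lectin, by 2.86 ± 0.26, Prok2, a secreted peptide, by 2.71 ± 0.17 and Msln, mesothelin, by 2.71 ± 0.20. The alternative-activation enzyme Arg1 rose by 2.26 ± 0.11 (adjusted p = 2.58e-08). Chemokines that attract monocytes rose too, Ccl2 by 1.86 ± 0.20 and Ccl7 by 1.38 ± 0.21 (adjusted p = 3.09e-05 and 0.000605). Genes that fell included the orphan nuclear receptors Nr4a3 (-2.08 ± 0.22), Nr4a1 (-1.95 ± 0.26) and Nr4a2 (-1.57 ± 0.17), the cartilage matrix genes Comp (-1.91 ± 0.18) and Chad (-1.84 ± 0.27), the amino acid transporter Slc6a14 (-1.85 ± 0.15) and the Wnt antagonist Sfrp2 (-1.61 ± 0.17). In all, 1351 probe sets rose and 1001 fell at an adjusted p under 0.05, 2352 together from 2225 genes. With the choroid plexus and neuron scores as covariates 803 rose and 855 fell, and 958 of the 2352 calls were kept. Il6 rose by 1.96 ± 0.53 (adjusted p = 0.027), but its values in the 3 stroke arrays were 6.30, 5.14 and 8.15. Its mean in every other group lay below the lower quartile of every array and was not shown to be above background. Differences of Il6 here and below are therefore not exact, and this rise is a lower bound. The Il6 call was lost without naive wild-type array 1, 2 or 3 (0.0642, 0.0595 and 0.0792) and without stroke wild-type array 3 (0.0888). It was also lost with only these arrays in the fit (0.114) and with the covariates (0.164). Kit fell by 0.57 on the log2 scale (SE 0.15, adjusted p = 0.0217), a call lost without naive array 2 (0.0967), without stroke array 2 or 3 (0.0664 and 0.0922), with only these arrays (0.0628), with the covariates (0.124) and without the 5 arrays lowest in Ttr (0.117).

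Gene lists fixed before the data were examined showed which groups moved with stroke in wild type. In the cell cycle list, 20 of 21 genes rose and 0 fell, and the same counts held adjusted over the list alone, among them Cdk1, the kinase that drives mitosis, by 2.10 ± 0.27, Aurkb by 1.58 ± 0.19, Mcm5 by 1.08 ± 0.15 and Cenpf by 1.08 ± 0.14. The median of that list was 1.08. Tested with camera, the list had an adjusted p of 1.2e-19, and adjusted p = 0.38 with an estimated correlation. Of 33 cytokine and chemokine genes, 13 rose, 1 fell and 19 did not pass, and adjusted over the list alone 18 rose and 1 fell, including Il11 by 1.56 ± 0.20, Ccl3 by 1.13 ± 0.14 and Tgfb1 by 0.73 ± 0.10. The camera adjusted p was 5.93e-09, with adjusted p = 0.126 with an estimated correlation. Monocyte and macrophage genes rose in 7 of 19 cases and in 9 when adjusted over the list alone, with Itgam at 0.81 ± 0.13 and Cd14 at 0.80 ± 0.12 beside Arg1. Camera gave this list an adjusted p of 0.000286, and adjusted p = 0.667 with an estimated correlation. In the mature neutrophil list 5 of 13 rose by either adjustment, over all genes and adjusted over the list alone, with Clec4e at 1.19 ± 0.19, Mmp9 at 1.14 ± 0.21, Il1r2 at 0.72 ± 0.13 and Trem1 at 0.63 ± 0.11. The list's camera adjusted p was 0.000515, against adjusted p = 0.667 with an estimated correlation. Markers of blood and marrow were measured beside it. Granulocyte precursor genes had a median of 0.33 with 0 of 10 passing and megakaryocyte and platelet genes a median of 0.33 with 0 of 8 passing, by either adjustment, over all genes or adjusted over the list alone. The precursor score was 0.94 in stroke array 2, one of the 5 arrays lowest in Ttr, and -0.20 in both other stroke arrays. Further markers were the erythroid list, with a median of -0.39 and 0 of 7 passing by either adjustment, over all genes or adjusted over the list alone, and the B cell list, where Vpreb1 rose (0.35 ± 0.08) and Ebf1 (-0.45 ± 0.12) and Cd79a (-0.68 ± 0.20) fell, or 1 rose and 3 fell of 11 adjusted over the list alone. The call of Ebf1 was lost without 2 and that of Cd79a without 4 of the 6 arrays (adjusted p at most 0.128 and 0.127). Adhesion and leukocyte entry genes rose in 5 of 10 cases, likewise 5 adjusted over the list alone, among them the leukocyte integrin Itgb2 at 0.82 ± 0.15 and the endothelial receptors Sele at 0.48 ± 0.09 and Icam1 at 0.48 ± 0.10. By camera the list had an adjusted p of 0.00982, and adjusted p = 0.665 with an estimated correlation. Neuron genes went the other way, with 4 of 9 lower and all 9 lower when adjusted over the list alone, a median of -0.77. As a set the list had a camera adjusted p of 4.88e-05, and adjusted p = 0.667 with an estimated correlation. Astrocyte genes split, with Gfap, the filament of reactive astrocytes, higher by 0.93 ± 0.21 and 3 of 8 lower, or 1 higher and 6 lower adjusted over the list alone. Tested with camera, the list had an adjusted p of 0.0112, and adjusted p = 0.667 with an estimated correlation. The neuron calls and the calls of the 3 lower astrocyte genes lay near the threshold and were lost with fewer arrays, while that of Gfap held without any single array. Of the neuron genes, Snap25 lost its call without naive array 1, 2 or 3 or stroke array 1 or 3 (adjusted p = 0.0678 to 0.154), Nefl and Gad1 without naive array 2 or 3 or stroke array 2 or 3 (0.0868 to 0.168 and 0.103 to 0.167) and Syn1 without naive array 3 or stroke array 1 or 3 (0.0729 to 0.117). Of the lower astrocyte genes, Aldoc lost it without naive array 2 or 3 or any stroke array (0.0557 to 0.137), Aqp4 without any naive array or stroke array 2 or 3 (0.0617 to 0.12) and Gjb6 without naive array 2 or 3 or stroke array 2 or 3 (0.0514 to 0.0638). In a list of keratinocyte genes chosen after the data were seen, 0 of 10 passed, with a median of 0.04, although Krtdap and the transglutaminase Tgm1 (2.28 ± 0.20) rose. Leaving out naive array 2 or 3 or stroke array 2 or 3 gave 1558, 1371, 1555 and 1429 called probe sets, only these arrays in the fit 1440, no arrays low in Ttr 1368 (where Gfap had an adjusted p of 0.0959) and a minimum change of 1.5-fold 756, while Icam1 had an adjusted p of 0.145 with the covariates.

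**Figure D2:**
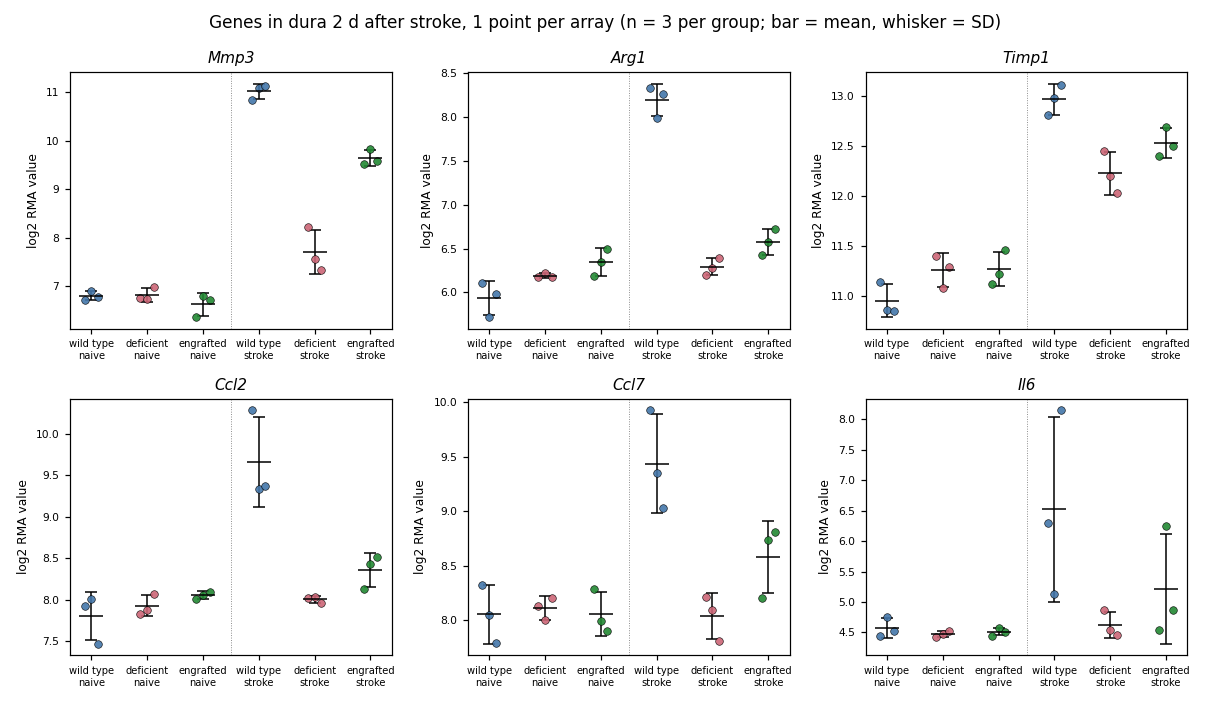
Log2 expression of genes named for their response to stroke (vertical axes, which differ in range) in each array, by category and treatment; points are arrays, bars are group means and whiskers are SDs (n = 3). Mmp3 rose from 6.80 to 11.01 in wild type, and reached 7.71 in deficient and 9.64 in engrafted dura after stroke.

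The same question was put to mast cell-deficient dura. Serpina3n, an acute-phase protease inhibitor, rose by 1.42 ± 0.16, Timp1, an inhibitor of metalloproteinases, by 0.97 ± 0.13 and Capg, an actin-capping protein of macrophages, by 0.74 ± 0.10 (adjusted p = 0.0035, 0.00718 and 0.00718). Nr4a3 (-1.81 ± 0.22), Nr4a2 (-1.24 ± 0.17) and Sfrp2 (-1.22 ± 0.17) fell, as they did in wild type. In total 27 probe sets rose and 27 fell. These 6 genes kept their calls without any single array, whereas the other 15 named genes that passed lost theirs without at least 1 array. Ccl7 stood at -0.07 ± 0.21 (adjusted p = 0.88), a sign that turned without stroke deficient array 3 (0.04) or without the 5 arrays lowest in Ttr (0.01). Il6 stood at 0.14 ± 0.53 (adjusted p = 0.908) and turned to -0.40 with the covariates. Both of its deficient means lay below the lower quartile of every array, so neither was shown to be above background. Kit stood at -0.33 ± 0.15 (adjusted p = 0.356). In the immediate early list, genes induced within minutes of a stimulus, 1 of 15 fell and 6 fell adjusted over the list alone, with a median of -0.42. The camera adjusted p was 3.92e-08, with adjusted p = 0.233 with an estimated correlation. Cell cycle genes had a median of 0.42 with 0 of 21 passing by either adjustment, over all genes or adjusted over the list alone, at camera adjusted p = 1.24e-06 and adjusted p = 0.86 with an estimated correlation. Neutrophil genes had a median of 0.38 with 0 of 13 passing over all genes and 4 higher adjusted over the list alone. Camera gave this list an adjusted p of 0.00116, and adjusted p = 0.86 with an estimated correlation. Granulocyte precursor genes, a marrow marker, had a median of 0.69 beside them, with 0 of 10 passing by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00216, adjusted p = 0.86 with an estimated correlation). The immediate early gene that passed, Nr4a1, lost its call without 4 of the 6 arrays (adjusted p = 0.0857 to 0.142). The count was unsteady: 30, 27 and 16 without naive array 1, 2 and 3, 8, 23 and 11 without stroke array 1, 2 and 3, 15 without the 5 arrays lowest in Ttr, 28 with a minimum change of 1.5-fold, 209 with the covariates and 1326 with array weights. With only these 6 arrays in the fit 1 probe set passed, and the 6 genes named above had adjusted p of 0.146 to 0.227. Timp1 and Sfrp2 also lost their calls without the 5 arrays lowest in Ttr (0.0852 and 0.132).

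In engrafted dura, stroke raised Mmp3 by 3.02 ± 0.18 (adjusted p = 4.36e-07), Vsig4, a complement receptor of resident macrophages, by 1.76 ± 0.20, Serpina3n by 1.75 ± 0.16 and Raet1d, a stress ligand, by 1.63 ± 0.17. Among genes that fell were Nr4a3 (-1.59 ± 0.22), Comp (-1.38 ± 0.18), Slc6a14 (-1.29 ± 0.15), the macrophage lectin Cd209d (-1.21 ± 0.14) and Sfrp2 (-1.20 ± 0.17). Altogether 190 probe sets rose and 51 fell. Granulocyte precursor genes had a median of 1.46, with 2 of 10 higher, Ctsg by 2.19 ± 0.42 and Prtn3 by 1.79 ± 0.31, both proteases of immature granulocytes, and 9 of 10 higher adjusted over the list alone. The list's camera adjusted p was 4.74e-13, against adjusted p = 0.193 with an estimated correlation. Both calls were lost without naive engrafted array 1 or 2 or stroke array 2 or 3 (adjusted p of 0.0867, 0.11, 0.101 and 0.114 for Ctsg and 0.0577, 0.0673, 0.0616 and 0.062 for Prtn3), and with only these arrays (0.128 and 0.117). Mature neutrophil genes had a median of 0.93, with 3 of 13 higher and 11 higher adjusted over the list alone. By camera the list had an adjusted p of 8.94e-13, and adjusted p = 0.193 with an estimated correlation. Cell cycle genes rose in 9 of 21 cases and in 20 adjusted over the list alone, with a median of 0.86. As a set the list had a camera adjusted p of 5.77e-27, and adjusted p = 0.193 with an estimated correlation. Ly6g and Cd177 of the neutrophil list and Mcm5, Mcm6, Cdk1 and Tyms of the cell cycle list each lost their calls without 4 of the 6 arrays, and Lcn2 without 1 (0.0644). The erythroid list, a marker of marrow and blood, had a median of 0.37 beside them, with 0 of 7 passing by either adjustment, over all genes or adjusted over the list alone. Tested with camera, the list had an adjusted p of 0.0283, and adjusted p = 0.582 with an estimated correlation. Ccl7 stood at 0.53 ± 0.21 (adjusted p = 0.333), Il6 at 0.71 ± 0.53 (adjusted p = 0.68) and Kit at 0.01 ± 0.15 (adjusted p = 0.991), the last with a sign that turned under several settings. The count of 241 fell to 70 and 60 without naive array 1 and 2, 76 and 88 without stroke array 2 and 3, 98 without the 5 arrays lowest in Ttr, 140 with a minimum change of 1.5-fold, 146 with the replicate block, 152 over all probe sets and 33 with only these arrays, and rose to 396 without stroke array 1, 394 with array weights and 521 with the covariates.

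Averaged over the 3 categories, stroke raised 1742 probe sets and lowered 1172. The largest rise was again that of Mmp3 (2.71 ± 0.10, adjusted p = 6.26e-10), followed by Krtdap (1.98 ± 0.14) and Chil3 (1.96 ± 0.24), a chitinase-like protein of macrophages and neutrophils. Serpina3n rose by 1.64 ± 0.09 and Vsig4 by 1.49 ± 0.11, while Nr4a3 (-1.83 ± 0.13), Nr4a1 (-1.49 ± 0.15), Comp (-1.46 ± 0.11) and Sfrp2 (-1.34 ± 0.10) fell. Ccl7 rose by 0.61 ± 0.12 (adjusted p = 0.00329) and Il6 stood at 0.94 ± 0.30 (adjusted p = 0.0536). In the mature neutrophil list 11 of 13 genes rose and 12 adjusted over the list alone, led by Lcn2, an iron-binding granule protein, at 1.25 ± 0.15. The camera adjusted p was 1.1e-08, with adjusted p = 0.34 with an estimated correlation. Granulocyte precursor genes rose in 8 of 10 cases, and in all 10 adjusted over the list alone. Camera gave this list an adjusted p of 2.22e-06, and adjusted p = 0.414 with an estimated correlation. Cell cycle genes rose in 20 of 21 cases by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 4.19e-22, adjusted p = 0.285 with an estimated correlation); for Top2a, a topoisomerase of dividing cells, at 1.45 ± 0.19, a further probe set had the opposite sign. Immediate early genes fell in 7 of 15 cases and rose in 1, or 8 and 2 adjusted over the list alone. The list's camera adjusted p was 0.00363, against adjusted p = 0.414 with an estimated correlation. Markers of platelets and of brain tissue moved beside these groups. Megakaryocyte and platelet genes rose in 3 of 8 cases, Itga2b by 0.39 ± 0.10, Gp9 by 0.51 ± 0.14 and Tubb1 by 0.52 ± 0.16, and in 5 adjusted over the list alone (camera adjusted p = 0.00703, adjusted p = 0.631 with an estimated correlation). Erythroid genes had a median of -0.04, with 0 of 7 passing by either adjustment, over all genes or adjusted over the list alone. Neuron genes fell in 5 of 9 cases and in 7 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 9.25e-05, adjusted p = 0.414 with an estimated correlation). Tubb1, Nefl, Nefm, Snap25 and Syn1 lost their calls without 10, 10, 7, 9 and 6 of the 18 arrays, and Itga2b and Gp9 without the 5 arrays lowest in Ttr (0.109 and 0.154). With the covariates 1496 probe sets rose and 1452 fell, and 1824 of the 2914 calls were kept. Leaving out the 5 arrays lowest in Ttr gave 1913 called probe sets and a minimum change of 1.5-fold 275. The Kit change of -0.30 ± 0.09 (adjusted p = 0.0317) lost its call without any of 7 arrays, namely naive wild-type array 2 (0.0564), naive deficient array 3 (0.0622), naive engrafted array 1 (0.0652), stroke wild-type array 2 and 3 (0.0551 and 0.0637) and stroke deficient array 1 and 3 (0.0559 and 0.0516), with the covariates (0.137) and without the 5 arrays lowest in Ttr (0.222).

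**Figure D3:**
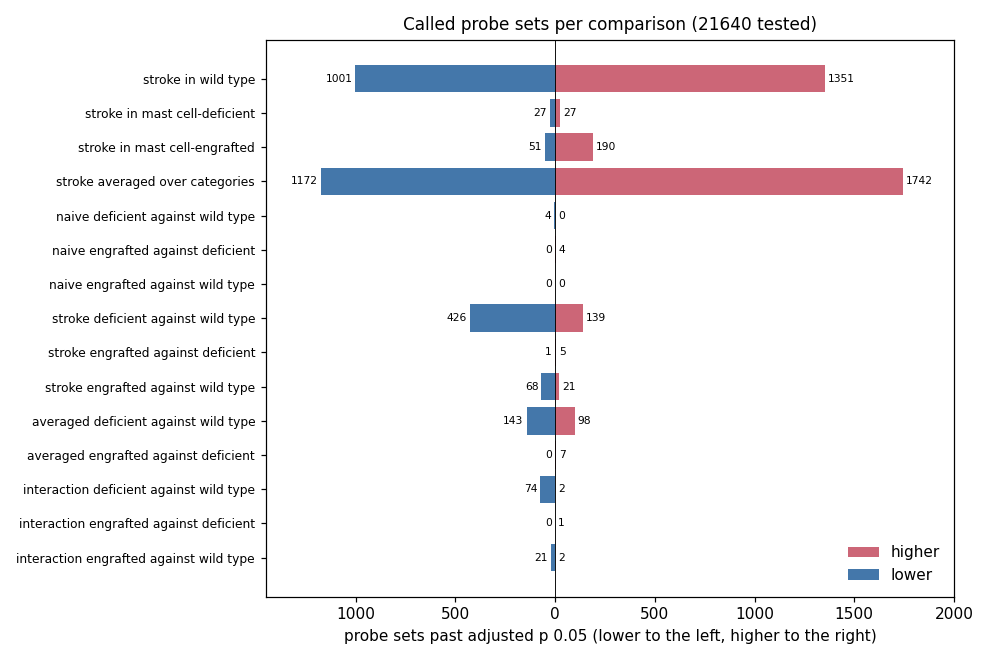
Number of probe sets that passed an adjusted p of 0.05 in each of 15 comparisons, out of 21640 tested, with higher probe sets to the right of 0 and lower ones to the left. Stroke in wild type gave 1351 higher and 1001 lower, against 27 and 27 in deficient and 190 and 51 in engrafted dura.

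Overlap between the responses was counted by gene, over 19938 genes. Of the 25 genes that rose and the 25 that fell in deficient dura, 22 and 18 were called in the same direction in wild type, where independent lists would share 1.59 and 1.13. For engrafted dura, 155 of 180 rising and 40 of 51 falling genes were shared with wild type, against 11.42 and 2.3 for independent lists. These responses use different arrays, so no control is shared. They do share 1 estimate of spread per probe set, taken from all 18 arrays. Probe sets with a small spread are thereby favoured in every category, so the numbers for independent lists are too low a baseline. With only the compared arrays in the fit, stroke in deficient dura called 1 probe set, which was not among the 54, and the overlap was not counted there. Genes that rose in wild type had a median change of 0.44 there, 0.16 in deficient and 0.19 in engrafted dura, and those that fell had medians of -0.46, -0.17 and -0.09. Because those genes were picked for their size in wild type, their medians elsewhere lie closer to 0 in part for that reason.

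Whether the response to stroke differs between deficient and wild-type mice was tested as an interaction. The response of Mmp3 was smaller in deficient dura by -3.33 ± 0.25 (log2, SE) and that of Arg1 by -2.16 ± 0.16, each with an adjusted p of 8.19e-06. Serpinb9b, a granzyme inhibitor, (-2.17 ± 0.23, adjusted p = 0.000521), Prok2 (-2.27 ± 0.25), Reg3g (-2.59 ± 0.37), Krtdap (-2.41 ± 0.34), Tgm1 (-1.93 ± 0.28), Raet1d (-1.94 ± 0.24) and Ccl2 (-1.78 ± 0.28, adjusted p = 0.00973) differed in the same sense. Slc6a14, which fell in wild type, had a positive interaction (1.45 ± 0.21). Of the 76 called probe sets, 74 were negative. Ccl7 had an interaction of -1.46 ± 0.30 (adjusted p = 0.0485), a call that ended without 10 of the 12 arrays left out in turn. Its adjusted p was 0.123 and 0.139 without naive wild-type array 2 and 3, 0.136, 0.0519 and 0.141 without naive deficient array 1, 2 and 3, 0.083 and 0.0935 without stroke wild-type array 1 and 2, and 0.0593, 0.117 and 0.157 without stroke deficient array 1, 2 and 3. The call of Ccl7 also ended with only these arrays (0.0755), the block (0.0631), a second quantile normalization (0.0521), the covariates (0.134) and no arrays low in Ttr (0.445). Il6 had an interaction of -1.81 ± 0.75 (adjusted p = 0.565). Among the cytokines and chemokines 3 of 33 responses were smaller, those of Ccl2, Ccl7 and Il11 (the last lost without 9 of the 12 arrays, adjusted p = 0.0607 to 0.136), and 9 adjusted over the list alone. By camera the list had an adjusted p of 2.22e-10, and adjusted p = 0.0759 with an estimated correlation. The cell cycle list had 0 of 21 passing over all genes and 11 smaller adjusted over the list alone, with a median of -0.70. As a set the list had a camera adjusted p of 2.51e-18, and adjusted p = 0.305 with an estimated correlation. Beside these groups, choroid plexus genes had a median interaction of 1.70 with 0 of 10 passing. The fit without the 5 arrays lowest in Ttr left naive deficient dura with 1 array. Its calls therefore cannot show whether these differences depend on choroid plexus tissue. The count was 46 with the replicate block, 305 with array weights, 117 without naive deficient array 2 and 41, 34, 43, 44, 38 and 31 without naive wild-type array 3, naive deficient array 1 and 3, stroke wild-type array 2 and stroke deficient array 2 and 3.

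The interaction between engrafted and deficient mice asked whether transferred mast cells change the response. Mmp3 rose more in engrafted than in deficient dura, by 2.14 ± 0.25 (adjusted p = 0.00683), and it was the only probe set of 21640 to pass, beside 2097 at an unadjusted p under 0.05. The call was lost with only these arrays in the fit (adjusted p = 0.201), which left 0 probe sets by limma, while array weights gave 2 and the covariates 3. Ccl7 had a value of 0.60 ± 0.30 (adjusted p = 0.523) and Il6 of 0.57 ± 0.75 (adjusted p = 0.786). Against wild type, the engrafted response was smaller for Arg1 (-2.03 ± 0.16, adjusted p = 3.75e-05), Serpinb9b (-1.81 ± 0.23), Prok2 (-1.95 ± 0.25) and an unnamed transcript, G530011O06Rik (-3.09 ± 0.39), each of which passed with any single array left out. In that comparison 21 probe sets were negative and 2 positive. The call of Prok2 was lost without the 5 arrays lowest in Ttr (0.149). This count of 23 went to 13, 9 and 12 without naive wild-type array 1, 2 and 3, to 8 and 8 without naive engrafted array 2 and 3, to 14 without stroke wild-type array 3, to 9, 52 and 12 without stroke engrafted array 1, 2 and 3, to 8 with the covariates or without the arrays lowest in Ttr, 9 without dim probe sets, 10 with only these arrays, 11 with the block and 42 with array weights.

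After stroke, the 3 categories were also compared directly. Deficient dura had less Mmp3 (-3.31 ± 0.18, adjusted p = 1.13e-07), Reg3g (-2.65 ± 0.26), Krtdap (-2.42 ± 0.24), Prok2 (-2.25 ± 0.17) and Arg1 (-1.90 ± 0.11) than wild type, besides Mcpt2 (-3.84 ± 0.35), Cpa3 (-3.21 ± 0.37) and Mcpt4 (-2.52 ± 0.37), the last 3 being lower bounds in size. Ccl2 was lower by -1.65 ± 0.20 (adjusted p = 0.000302) and Ccl7 by -1.40 ± 0.21 (adjusted p = 0.00182, and 0.0649 without the 5 arrays lowest in Ttr). Hmox1, the haem-degrading enzyme, was lower by -1.33 ± 0.17 (adjusted p = 0.000416), while Il6 stood at -1.91 ± 0.53 (adjusted p = 0.0761). The Il6 difference is a lower bound in size, since its deficient mean lay below the lower quartile of every array. Higher in deficient dura were Slc6a14 (1.60 ± 0.15), Comp (1.41 ± 0.18), Chrdl1, an antagonist of bone morphogenetic proteins, (1.31 ± 0.15) and Egfl6 (1.04 ± 0.12). There were 139 higher and 426 lower probe sets. Cell cycle genes were lower in 14 of 21 cases and in 20 adjusted over the list alone, with a median of -0.91. Tested with camera, the list had an adjusted p of 6.89e-22, and adjusted p = 0.16 with an estimated correlation. Mature neutrophil genes were lower in 3 of 13 cases, Clec4e by -1.09 ± 0.19, Il1r2 by -0.72 ± 0.13 and Trem1 by -0.63 ± 0.11, and in 9 adjusted over the list alone. The camera adjusted p was 7.97e-10, with adjusted p = 0.174 with an estimated correlation. Of 33 cytokines and chemokines 7 were lower and 1 higher, or 13 and 2 adjusted over the list alone. Camera gave this list an adjusted p of 1.01e-06, and adjusted p = 0.16 with an estimated correlation. Brain tissue markers were measured beside them. Neuron genes had a median of 0.53, with 0 of 9 passing by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.000491, adjusted p = 0.475 with an estimated correlation). Myelinating glia genes had a median of 0.27, with 1 of 7 higher, Mbp by 0.74 ± 0.18 (adjusted p = 0.0361), and 2 adjusted over the list alone (camera adjusted p = 0.000833, adjusted p = 0.353 with an estimated correlation). The call of Mbp was lost without 4 of the 6 arrays, namely stroke wild-type array 1 and 3 (0.113 and 0.169) and stroke deficient array 2 and 3 (0.0976 and 0.191). Of the cell cycle genes, Aurkb, Tpx2 and Cdc20 lost their calls without 2 of the 6 arrays and Cenpf without 4 (0.0593 to 0.0885). The count of 565 became 321 and 298 without stroke wild-type array 1 and 3, 246 and 226 without stroke deficient array 2 and 3, 222 with only these arrays, 341 with the covariates, 95 without the 5 arrays lowest in Ttr (where Clec4e, Il1r2 and Trem1 had adjusted p of 0.0721, 0.111 and 0.0842) and 1743 with array weights.

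In engrafted compared with deficient dura after stroke, Mcpt2 was higher by at least 4.39 ± 0.35, Cpa3 by at least 3.91 ± 0.37, Mcpt4 by at least 2.92 ± 0.37 and Mmp3 by 1.94 ± 0.18 (adjusted p = 0.00012). Fcer1a, a chain of the IgE receptor of mast cells and basophils, was higher by 1.26 ± 0.18 (adjusted p = 0.0152) and Slc6a14 lower by -1.07 ± 0.15 (adjusted p = 0.0105). These 6 were all that passed, beside 1359 at an unadjusted p under 0.05. Granulocyte precursor, mature neutrophil and cell cycle genes had medians of 1.25, 1.01 and 0.58, with 0 of 10, 0 of 13 and 0 of 21 passing over all genes and 8, 12 and 17 higher adjusted over the list alone. Their camera adjusted p were 7.53e-16, 3.46e-18 and 3.42e-20, with adjusted p = 0.0781, 0.0781 and 0.102 with an estimated correlation. Erythroid genes moved with them, at a median of 0.66 with 0 of 7 passing over all genes and 5 higher adjusted over the list alone. The list's camera adjusted p was 1.18e-08, against adjusted p = 0.093 with an estimated correlation. Against wild type, engrafted dura after stroke had lower Reg3g (-2.36 ± 0.26), Prok2 (-1.81 ± 0.17), Serpinb9b (-1.81 ± 0.16), Arg1 (-1.62 ± 0.11, adjusted p = 6.77e-06) and Mmp3 (-1.37 ± 0.18, adjusted p = 0.00214), with 68 probe sets lower and 21 higher. Neuron genes were higher there, with a median of 0.74, 0 of 9 passing over all genes and all 9 passing adjusted over the list alone. By camera the list had an adjusted p of 4.69e-09, and adjusted p = 0.189 with an estimated correlation. Ccl7 stood at -0.85 ± 0.21 (adjusted p = 0.0986) and Il6 at -1.31 ± 0.53 (adjusted p = 0.327). With only these arrays in the fit, limma called 0 probe sets against wild type, where Arg1 had an adjusted p of 0.0515, and against deficient dura Mmp3, Fcer1a and Slc6a14 had 0.149, 0.0704 and 0.858. Fcer1a lost its call without stroke deficient array 1, 2 or 3 (0.0706, 0.149 and 0.0934) or stroke engrafted array 2 or 3 (0.0782 and 0.0685), Slc6a14 without stroke deficient array 3 (0.0526) or stroke engrafted array 3 (0.0698). Without the 5 arrays lowest in Ttr, Fcer1a and Slc6a14 had 0.165 and 0.178, and Mmp3 against wild type 0.0509, beside 0.137 with the covariates. The count of 6 went to 39 and 10 without stroke engrafted array 1 and 2 and to 14 with the covariates, and that of 89 to 57 and 29 without stroke wild-type array 2 and 3, 54, 333 and 40 without stroke engrafted array 1, 2 and 3, 57 with the block, 28 without the arrays lowest in Ttr, 13 with the covariates and 199 with array weights.

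Averaging naive and stroke dura gave the question of which differences from wild type engraftment undoes. Deficient dura had lower Mcpt2 (-4.28 ± 0.25), Cpa3 (-3.44 ± 0.26), Mcpt4 (-3.03 ± 0.26), Mmp3 (-1.65 ± 0.12), Tpsb2 (-1.03 ± 0.12) and Tpsab1, a further tryptase (-0.82 ± 0.09), than wild type. Here too the differences of Mcpt2, Cpa3 and Mcpt4 from deficient dura are lower bounds in size. Comp (1.00 ± 0.13), Chrdl1 (0.89 ± 0.10) and Slc6a14 (0.88 ± 0.10) were higher, and Kit stood at -0.39 ± 0.10 (adjusted p = 0.0907). In total 98 probe sets were higher and 143 lower. The mast cell list had 8 of 22 genes lower and 14 adjusted over the list alone. As a set the list had a camera adjusted p of 6.26e-14, and adjusted p = 0.057 with an estimated correlation. Mature neutrophil genes were lower in 7 of 13 cases and in 12 adjusted over the list alone, with a median of -0.92. Tested with camera, the list had an adjusted p of 9.98e-13, and adjusted p = 0.235 with an estimated correlation. Engrafted dura had higher Mcpt2 (4.46 ± 0.25), Cpa3 (3.97 ± 0.26), Mcpt4 (3.24 ± 0.26), Fcer1a (1.07 ± 0.13), Tpsb2 (1.06 ± 0.12), Mmp3 (0.87 ± 0.12) and Tpsab1 (0.62 ± 0.09) than deficient dura, and no other probe set passed, beside 575 at an unadjusted p under 0.05. This number of 575 lay below the 1082 expected if nothing differed. In the mast cell list 6 of 22 rose and 14 adjusted over the list alone. The camera adjusted p was 3.29e-45, with adjusted p = 0.000309 with an estimated correlation. Neutrophil, granulocyte precursor and erythroid genes had medians of 0.71, 0.93 and 0.58, with 0 passing over all genes and 12 of 13, 10 of 10 and 7 of 7 higher adjusted over the list alone; their adjusted p with an estimated correlation were 0.0147, 0.0178 and 0.0178.

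In the averaged comparison of deficient with wild-type dura, the neutrophil genes Cxcr2, Retnlg, Lcn2, Clec4e and Mmp8 lost their calls without 7, 9, 5, 5 and 5 of the 12 arrays (adjusted p at most 0.0719, 0.105, 0.0676, 0.0642 and 0.0642), and the mast cell genes Hdc and Mrgprb1 without 8 and 10 (at most 0.088 and 0.103). In the averaged engrafted comparison, Fcer1a and Tpsab1 lost their calls with only these arrays (adjusted p = 0.0531 and 0.0872) and without the 5 arrays lowest in Ttr (0.058 and 0.224). Exactly 6 probe sets were lower in deficient than in wild-type dura and higher after engraftment, those of Mcpt2, Cpa3, Mcpt4, Tpsb2, Tpsab1 and Mmp3, and 0 had the opposite pattern. Mmp3 was not called in naive deficient against wild-type dura. Its stroke response was smaller in deficient dura by -3.325, so its averaged difference of -1.65 came from dura after stroke. Engraftment undid part of the Mmp3 difference (0.87). Both averaged differences share the deficient arrays. In 50 simulations of unchanged groups sharing those arrays, 0 probe sets had the pattern. With no difference simulated, hardly any probe set can pass in either comparison, so this 0 does not test the effect of the shared arrays. Independent lists would share 0.046. With the deficient arrays split between the differences, 18 splits gave 3 to 6. The covariance of the differences over all probe sets was -0.0066, beside -0.0047 from the shared arrays alone. Opposite signs were found in 54.6% of all probe sets, fewer than the 66.7% of simulated unchanged groups that share those arrays. Mmp3 lost its call against engrafted dura without naive deficient array 1 or 2, naive engrafted array 2 or stroke deficient array 2 (adjusted p = 0.0574, 0.0513, 0.059 and 0.0511), with only these arrays (0.16) and without the 5 arrays lowest in Ttr (0.877), a setting that left 4 restored probe sets. The count of 241 against wild type went to 49 without those arrays, 80 with a minimum change of 1.5-fold, 144 with the covariates, 145 with the block, 158 over all probe sets, 1444 with array weights, 145 and 109 without naive wild-type array 1 and 3, 148 and 126 without naive deficient array 1 and 3, 154 and 137 without stroke wild-type array 1 and 3, and 365, 99 and 122 without stroke deficient array 1, 2 and 3; that of 7 went to 18 and 11 without stroke engrafted array 1 and 2, 4 with only these arrays or without dim probe sets and 12 with array weights, and that of 6 to 11 without stroke engrafted array 1 and 10 with array weights.

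Samples also differed in genes of the choroid plexus, a tissue that may have been carried along with the dura. Ttr, the thyroid hormone carrier that choroid plexus secretes, lay between 9.03 and 10.17 in 5 arrays and between 13.03 and 13.78 in the other 13. These 5 were naive deficient array 1 and 3, naive engrafted array 3, stroke wild-type array 2 and stroke deficient array 2. Htr2c, a serotonin receptor of the same tissue, followed, with at most 7.02 in those arrays and at least 9.03 in the others. None of the 10 choroid plexus genes passed limma's threshold in any of the 15 comparisons.

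**Figure D4:**
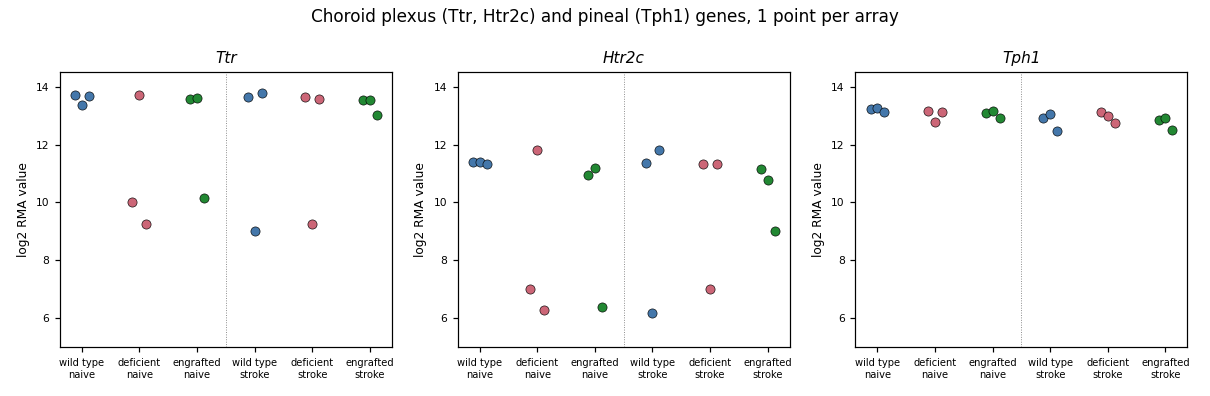
Log2 expression of Ttr and Htr2c (choroid plexus) and Tph1 (pineal gland) on a shared vertical axis in each of the 18 arrays, by category and treatment; each point is an array. Ttr lay between 9.03 and 10.17 in 5 arrays from 4 groups, while Tph1 was high in all 18.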

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

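The tests of the interaction with other tissue as covariates, of single arrays left out and of the share recovered by engraftment were chosen after the result was seen, and the criterion of the last was changed after its value was seen, while the interaction tests and the splits of the arrays were planned.

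Responses to stroke that differed between categories by a test of the difference itself are given here. Against wild type, deficient dura had 76 such probe sets and 11 gene lists called by camera; engrafted against deficient dura had 1 and 9, and engrafted against wild type 23 and 11. With an estimated correlation limma's camera called 0 of those lists in each of the 3 comparisons, and fry also called 0. In deficient against wild-type dura the differences were -3.33 for Mmp3, -2.59 for Reg3g, -2.41 for Krtdap, -2.27 for Prok2, -2.17 for Serpinb9b, -2.16 for Arg1, -1.94 for Raet1d, -1.94 for G530011O06Rik, -1.93 for Tgm1, -1.78 for Ccl2 and -1.46 for Ccl7, with 1.45 for Slc6a14 and 0.64 for Gm10706. In engrafted against deficient dura, Mmp3 differed by 2.14. In engrafted against wild-type dura the differences were -3.09 for G530011O06Rik, -2.24 for Reg3g, -2.03 for Arg1, -1.95 for Prok2, -1.81 for Serpinb9b, -1.78 for Tgm1, -1.56 for Ccl2, -1.36 for Dmkn, -1.35 for Hmox1 and -1.31 for Tfpi2, with 1.33 for Arxes2 and 1.06 for Arxes1. Many of these calls lay near the threshold and were lost with fewer arrays. Against wild type, deficient dura lost those of G530011O06Rik, Ccl7 and Gm10706 without 11, 10 and 9 of the 12 arrays. Engrafted dura lost those of Reg3g, Ccl2, Hmox1 and Arxes1 without 9 each, Arxes2 without 8, Tgm1 without 7, Dmkn without 6 and Tfpi2 without 5.

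The larger response to stroke in wild-type than in deficient dura was weighed against technical explanations. With choroid plexus and neuron scores as covariates the median ratio of the 76 interactions to those without them was 0.929. This argues against choroid plexus and neuronal tissue as the whole cause, although only 45 of the 76 were still called. Other tissue, such as marrow, was not in that fit and is not covered. Without each of the 12 arrays in turn at least 31 probe sets were called, against 0 in splits that kept no real division, which argues against 1 aberrant array as the whole cause. Mast cells raising the response is a candidate explanation that stays open: engrafted dura recovered a median of 0.278 of the difference, under the 0.3 first set as arguing against it, but after that value was seen the criterion was changed to the range with single arrays left out, 0.221 to 0.316. Since the choice of probe sets and the shared deficient arrays move this share, it was simulated. No recovery gave a median of 0.12 (-0.153 to 0.553) with the observed size or more in 10 of 100 draws. Full recovery gave 0.845 (0.462 to 1.14), with the observed size or less in 0 of 100 draws. Draws without recovery called a median of 253 probe sets against the real 76. Both cases simulated wild-type and deficient dura alike and picked probe sets from them in the same way, so this mismatch limits both. The shares of neither case are directly comparable with the observed 0.278. An effect of the Kit genotype apart from mast cells had no test of its own on this pattern. Engrafted mice carry the same Kit alleles, so their response bears on it. Against wild type it gave 23 called probe sets, 21 of them negative. The share recovered, limited as above, does not decide between genotype and mast cells.

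Other splits of the arrays were compared with the real one. For deficient against wild type, 7 of 100 splits gave as many as the real 76, with 225 as the highest other, so chance was not excluded; the 6 others kept the real division of the naive or the stroke arrays, and the highest without it was 0. For engrafted against deficient, 8 of 100 gave at least 1, with 76 as the highest other, so chance was not excluded. That split kept no real division and called 76 against the real 1, and whether a structure of the arrays lies behind it was not tested. Of the 7 other splits that gave at least 1, 5 kept a real division. For engrafted against wild type, 2 of 100 gave at least 23, with 272 as the highest other. That split kept a real division, and the highest without it was 0, as for deficient against wild type. The shares of the comparisons with wild type differ only through splits that kept a real division, so chance is not called excluded here.

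Among the 13120 probe sets outside the comparisons, stroke called 638 in wild-type, 13 in deficient and 16 in engrafted dura, and 760 averaged over categories. Of these, 1321 had several gene symbols and 11799 were not in the annotation, and the groups of 3 arrays are too small for a test of single samples.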

How the results depend on the processing

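The fits with choroid plexus and neuron scores as covariates and without the 5 arrays lowest in Ttr were chosen after the data were seen, as was the extension of the genes refitted; the other alternatives were planned. Of 12579 alternative values for 748 pairs of a gene under the naming rule and a comparison, a subset of all genes that passed, 10988 kept their direction and side of the threshold, 1264 lost a call, 316 gained one and 11 turned direction. Named genes kept their calls without each array in 55 of 85 cases for stroke in wild type, 6 of 21 in deficient, 17 of 36 in engrafted dura and 71 of 87 averaged. Of the 748 pairs, 157 lost a call without the 5 arrays lowest in Ttr and 126 with only the compared groups in the fit. Signal over background limits dim genes; 13186 tested probe sets lay above the median of the table, 7.83. The cause was not tested except where fewer arrays or probe sets entered the fit.

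With only the compared groups in the fit, counts were 1440, 1 and 33 for stroke in wild-type, deficient and engrafted dura, 0 for naive engrafted against deficient, 3 for naive engrafted against wild type, 222 and 0 for deficient and engrafted against wild type after stroke, 4 for averaged engrafted against deficient, and 0 and 10 for the interactions of engrafted with deficient and with wild type. Without the 5 arrays lowest in Ttr, stroke gave 1368, 15, 98 and averaged 1913, naive engrafted against wild type 1, deficient and engrafted against wild type after stroke 95 and 28, averaged deficient against wild type 49 and the interactions 6, 0 and 8. A minimum change of 1.5-fold gave 756, 28, 140 and 275 for stroke and 80 for averaged deficient against wild type.

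Array weights gave 1326 and 394 for stroke in deficient and engrafted dura, 36, 8 and 164 for the naive comparisons, 1743 and 199 for deficient and engrafted against wild type after stroke, 1444 and 12 for the averaged comparisons, 305, 2 and 42 for the interactions and 10 for the restored probe sets. The covariates gave 209 and 521 for stroke in deficient and engrafted dura, 20 for naive engrafted against wild type, 341, 14 and 13 for the comparisons after stroke, 144 for averaged deficient against wild type and 3 and 8 for the interactions of engrafted dura. All probe sets gave 152 for stroke in engrafted dura and 158 for averaged deficient against wild type. Without dim probe sets, naive engrafted against wild type gave 1, averaged engrafted against deficient 4 and the interaction of engrafted with wild type 9. A second quantile normalization gave 4 and the trended variance 1 for naive engrafted against wild type. Of 172 camera calls with the preset correlation over 435 list and comparison pairs, an estimated correlation gave 11 and fry 49.

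Replicate numbers pair no arrays by the labels, and 0 of 15 pairs of groups had every correlation over 0.1 (-0.609 to 0.603, median -0.056), so arrays share only a number. With the replicate block, stroke in engrafted dura gave 146, naive engrafted against wild type 2, engrafted against wild type after stroke 57, averaged deficient against wild type 145 and the interactions of deficient and of engrafted with wild type 46 and 11; it moved no other count by over 1.5 times.

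With each array left out in turn, counts ranged from 1371 to 2211 for stroke in wild type, 8 to 30 in deficient, 60 to 396 in engrafted dura and 2182 to 2842 averaged; 3 to 10, 3 to 7 and 0 to 6 for naive deficient against wild type, engrafted against deficient and engrafted against wild type; 226 to 593, 4 to 39 and 29 to 333 for the same after stroke; 99 to 365 and 6 to 18 for the averaged comparisons; 31 to 117, 1 to 1 and 8 to 52 for the interactions; and 5 to 11 for the restored probe sets.

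Values that turned direction were those of Nefl in wild type (0.001) and Rbfox3 in engrafted against wild-type dura after stroke (-0.107), both with the covariates, whose neuron score contains them; of Il6 in deficient dura with the covariates (-0.395); of Ccl7 in deficient dura without the 5 arrays lowest in Ttr (0.010) and, over single arrays left out, from -0.161 to 0.042, the latter without stroke array 3; and of Kit in engrafted dura with a second quantile normalization (-0.014), without the 5 arrays lowest in Ttr (-0.006), without naive array 2 and 3 (-0.009 and -0.006) and without stroke array 1 and 3 (-0.073 and -0.084). Over single arrays left out, Kit there ranged from -0.084 to 0.193.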

Other observations

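The tests of choroid plexus genes and of bone marrow carried along were chosen after the results were seen, while the test of the Kit genotype and the splits of the arrays were planned.

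Genes of the circadian clock moved in both directions with stroke averaged over categories. Dbp, a clock output factor, rose by 0.85 ± 0.08 (log2, SE) and Per3 by 0.50 ± 0.08, while Arntl, the partner of Clock, changed by -0.57 ± 0.07 and Nfil3, a repressor of the genes that Dbp activates, by -0.42 ± 0.07 (adjusted p = 5.14e-06, 0.000831, 5.68e-05 and 0.000893). Of 15 measured clock genes 7 rose and 5 fell, or 8 and 5 adjusted over the list alone, and the list as a whole did not move one way (median 0.11, camera adjusted p = 0.746). Times of day at which dura was taken were not given in the sources used here. Among glucocorticoid response genes 3 of 14 rose and 5 fell, the same counts adjusted over the list alone, with Errfi1 at -0.34 ± 0.05, Per1 at -0.50 ± 0.10 and Tsc22d3 at -0.38 ± 0.08.

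Complement genes also moved with stroke averaged over categories, with 7 of 12 higher and 3 lower by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.0604). C4b, a component of the classical pathway, rose by 0.47 ± 0.06 and C3ar1, the receptor of a C3 fragment, by 0.53 ± 0.07 (adjusted p = 4.5e-05 and 0.000136). Interferon genes did not pass in any of 16 cases. Aldh1a2, which makes retinoic acid, was lower in deficient than in wild-type dura after stroke (-0.98 ± 0.15, adjusted p = 0.00275), and so was the retinoic acid carrier Crabp2 (-0.77 ± 0.13, adjusted p = 0.00516).

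Choroid plexus genes were low in 5 of the 18 arrays, from 4 groups. For 9 of the 10 markers these 5 arrays were the lowest, which is consistent with choroid plexus tissue present in some samples and absent from others. In any comparison, 0 of the 10 passed limma's threshold. Levels so far apart within groups of 3 arrays hide a difference between groups, so this cannot decide on an effect of category or stroke. Naive deficient array 1 and 3 and stroke deficient array 2 were among the 5. Stroke engrafted array 3 lay between, with a mean list score of -0.97 against at least 0.53 in the other 12 arrays and at most -2.20 in the 5, which a division into present and absent does not describe. Ttr ranged from 9.03 to 10.17 in the 5 and was at least 13.03 in the others, Htr2c at most 7.02 and at least 9.03.

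The mean score of mature neutrophil genes differed by -0.75 ± 0.18 between deficient and wild-type dura (camera adjusted p = 9.98e-13, adjusted p = 0.235 with an estimated correlation). Of 13 genes 7 passed; each of the 5 that were refitted lost its call without 5 to 9 of the 12 arrays, and the other 2 were not refitted. For bone marrow carried along, 2 of 3 other marrow lists (B cell 0.10 ± 0.09, erythroid 0.00 ± 0.21, an average of -0.27 in naive dura and 0.28 after stroke, megakaryocyte 0.05 ± 0.15) lay above 0.5 times that difference by more than 2 SE, and granulocyte precursor genes, another marrow list, moved in the direction of the neutrophil genes (-0.35 ± 0.23), so marrow carried along stays open. For the Kit genotype alone, the neutrophil score was 0.65 ± 0.18 higher in engrafted than in deficient dura. With granulocyte precursor and erythroid scores as covariates it was 0.119 ± 0.13 higher (wild type above deficient by 0.64 ± 0.11). Both covariate scores were themselves higher in engrafted than in deficient dura (0.78 ± 0.23 and 0.65 ± 0.21). Fitting them can remove part of the difference under test, so the adjusted value cannot decide and the genotype explanation stays open.

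Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real count and the highest of the other splits were 2352 and 0 for stroke in wild type, 54 and 0 in deficient and 241 and 6 in engrafted dura. They were 4 and 0 for naive deficient against wild type, 4 and 0 for naive engrafted against deficient and 0 and 0 for naive engrafted against wild type, where all 10 splits gave as many. They were 565 and 0 for deficient against wild type after stroke, 6 and 0 for engrafted against deficient and 89 and 6 for engrafted against wild type. In the others only 1 split, the real one, gave as many. Of 100 splits only 1, the real one, gave as many for stroke averaged over categories (2914, highest other 1219, a split that kept a real division). The same held for averaged deficient against wild type (241, highest other 225) and averaged engrafted against deficient (7, highest other 1). It also held for the 6 probe sets lower without mast cells and restored (highest other 0). Each share was under 0.05. Apart from Mmp3, those 6 are mast cell proteases, in which the categories differ by design. The share of the 6 therefore does not test Mmp3 by itself.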
